A study of Homo sapiens with 4 samples.

How the data were processed

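Poly(A)-selected RNA from 4 cultures or preparations labelled HepG2 was sequenced as directional libraries, 2 from wild-type cells and 2 from cells in which SMUG1 had been edited at its start codon with CRISPR/Cas9. HepG2 is a human hepatoblastoma-derived line, and SMUG1 encodes a DNA glycosylase that removes uracil and 5-hydroxymethyluracil. Nothing in the labels says whether the libraries of a group came from separate cultures, or how many edited clones were used, so the p-values measure only the spread between these libraries, which may be technical. Groups and replicate numbers were taken from the sample titles. The 2 libraries of a group were not duplicates: over genes with 20 or more counts in the pair, chi-square per degree of freedom was 2.04 for wild type and 1.41 for knockout.

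The authors deposited whole-number read counts per Ensembl transcript for 226788 transcript IDs. Per the submitters' processing notes the build was GRCh38 and the tools were CASAVA, DESeq2, limma and edgeR, with no versions or roles. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Totals were 1301088 and 1139096 counts in the wild-type libraries and 1520057 and 1500700 in the knockout libraries. The authors also deposited FPKM values (fragments per kilobase and library depth). For 92.5% to 93.2% of detected transcripts these lay within 1% of the count divided by transcript length, a median-of-ratios size factor and the geometric mean of the totals.

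The way reads were counted limits what could be seen. Transcripts without an exonic base of their own in GENCODE 29 made up 34.2% of the annotated transcripts in the table but held 0.491% of the counts, and 0.468% of them had any count, against 40.0% of the others. ACTB had 31 counts and GAPDH 37 over all 4 libraries. The counts therefore behave as reads that could be placed on a single transcript, and a gene's count reflects only the parts that set 1 of its transcripts apart. For 1676 of the 6638 protein-coding genes tested, the most counted transcript was not itself protein coding. Reads shared between near-identical copies, or between overlapping genes, cannot be assigned with certainty.

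The tests had been planned per gene, so transcript counts were summed per gene, and the table as deposited was tested as an alternative chosen after seeing the data. Gene models and coordinates came from GENCODE 29 on GRCh38, and current symbols were matched for 58207 gene IDs. In the table, 205999 transcript IDs were in that annotation. The others held 0.506% to 0.584% of the counts of a library and were left out of gene sums. Every per-sample column was mapped to a sample.

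Gene counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 8568 genes with 97.2% of the gene counts. Libraries were scaled by TMM factors, and the groups were compared with edgeR's quasi-likelihood F test with robust shrinkage and no covariates. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All adjusted p-values of single genes below come from this test unless another is named. The standard error of a log2 fold change (SE) was taken as its size divided by the square root of F. Levels are TMM-scaled CPM (counts scaled to a library of 1e06), as mean ± SD over 2 libraries.

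In total, 44 gene lists were fixed before the data were examined. Lists with 5 or more tested members were compared with the remaining genes by camera with a preset inter-gene correlation of 0.01, adjusted over 26 lists. Chromosomes with 20 or more tested genes were compared in the same way. Named genes were chosen by a rule fixed at the same time: SMUG1, then the 12 largest rises and 12 largest falls among protein-coding genes past the threshold whose knockout libraries both lay beyond both wild-type libraries and whose higher group averaged at least 10 CPM. Clone and locus names were excluded. For each list, up to 2 members that rose most and up to 2 that fell most were added, or the 2 most abundant members where none passed. Not every gene that this rule names is reported here. A few further genes were chosen after their values were seen, and the text says so.

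The pipeline was tested on simulated data for the comparison of knockout with wild type, with 8568 genes and 200 changed genes in each of 5 simulations. It recovered 26.2% of genes changed 1.5-fold, 60.6% of those changed 2-fold and 88.6% of those changed 4-fold, and 5.61% of its calls were false. Camera found 5 of 5 simulated lists of 20 genes shifted by 0.6 on the log2 scale and none of 100 unshifted lists. Simulated genes varied independently around edgeR's own dispersions, with no regional shift or GC trend. The rates therefore do not measure the error among the real calls.

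Alternatives covered DESeq2's size factors, library size alone, removal of the 20 most abundant genes, 2 other filters, DESeq2 1.42.0, limma-voom, edgeR without robust shrinkage, limma-trend on log2(FPKM + 1), removal of each library, a replicate block, a threshold of 0.01, glmTreat against a 1.5-fold change and 3 other list tests. Genes to which DESeq2's independent filter gave no adjusted p (3156 of 8568) were not counted as lost calls. Added after seeing the data were transcripts as deposited, protein-coding genes led by a protein-coding transcript, loess offsets for GC content and length, and regional centring, which takes the median log2 fold change of the nearest 50 genes on the chromosome as an offset. Intervals and floors, at 3 counts for a count of 0, cover counting error only.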

Results

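The data set held 4 poly(A)-selected RNA-seq libraries from cells labelled HepG2, 2 from wild-type cells and 2 from SMUG1-knockout cells. The comparison asks how the transcriptome differed between cells with and without an edited SMUG1 gene. Each library had between 1139096 and 1520057 counts, and 19516 to 21939 genes were detected per library. Across the genes tested, log2 CPM correlated at 0.971 between the wild-type libraries and at 0.980 between the knockout libraries, against 0.933 to 0.940 across groups. Genes are not independent replicates in such correlations.

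Knockout and wild-type libraries differed in 2170 of 8568 genes, with 943 genes higher and 1227 lower in knockout. In these poly(A)-selected libraries histone genes led the rises, up to 16.5-fold for HIST2H2AA3. The growth factor gene BMP2 fell 15.1-fold, and TNFRSF10D, of the death receptor family, had no count left in knockout. Of 10 heat shock genes tested 5 fell and 0 rose, and of 36 ribosomal protein genes 13 fell and 0 rose. Both lists were past camera's threshold, and both had adjusted p = 0.667 with an estimated correlation and 0.0774 with fry. A change of 2-fold or more was seen in 332 higher and 296 lower genes. Protein-coding genes made up 771 of the rises and 974 of the falls, and pseudogenes 69 and 191. In 5300 genes (61.9%) both knockout libraries lay beyond both wild-type libraries, where chance gives 33.3%. DESeq2 called 806 genes, 256 higher and 550 lower, and without the first or second knockout library edgeR called 1336 or 1275. Scaled by library size alone, 1141 genes were higher and 1095 lower. Across genes, which are not independent replicates, log2 fold changes followed GC content (Spearman 0.25), with medians of -0.17 in the lowest and 0.30 in the highest eighth of GC content. With offsets for GC content and length, 2275 genes were called, of which 1846 were among the 2170.

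**Figure D1:**
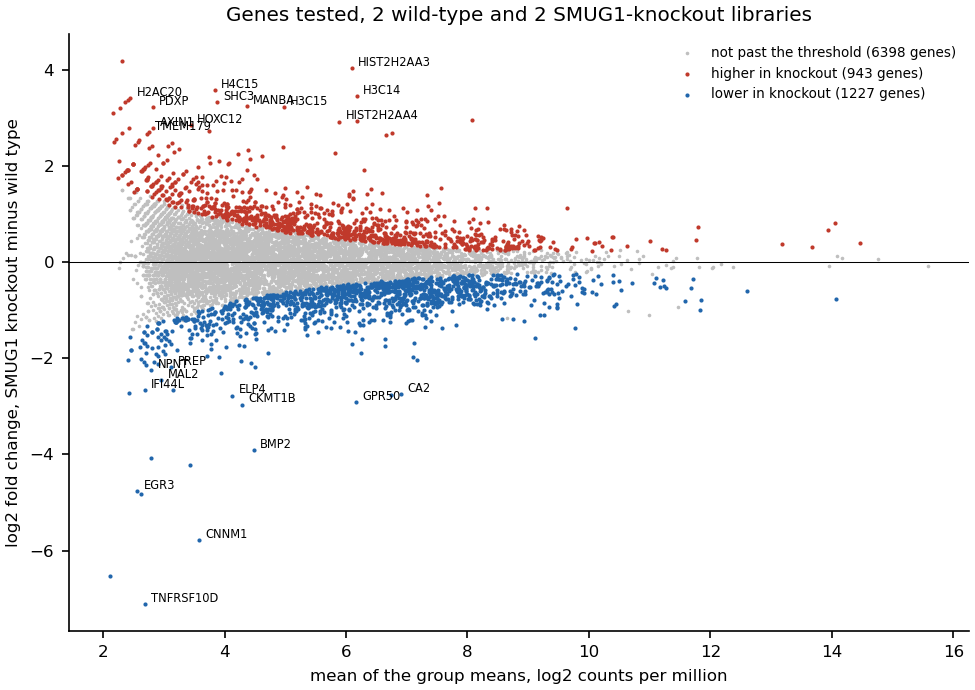
Each point is 1 of 8568 tested genes, with the mean of the group means in log2 CPM on the x axis and the log2 fold change, knockout minus wild type, on the y axis. The 943 higher genes are red, the 1227 lower genes blue, and the named genes are labelled; fitted values of genes with near-zero counts in 1 group, such as TNFRSF10D, depend on a prior count.

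SMUG1 transcript counts did not separate the groups. The gene lies on chromosome 12 from 54121277 to 54189008 on the minus strand of GRCh38. It had 31 and 33 counts in the wild-type libraries and 49 and 40 in the knockout libraries, or 27.7 ± 3.44 CPM against 30.0 ± 3.33 CPM (SD, n = 2). The log2 fold change was 0.12 (SE 0.25, adjusted p = 0.760, edgeR). These counts do not check the edit: the annotated start codon, at 54183938 to 54183940, lies in exons of 18 annotated transcripts, so it has no base that a single transcript owns. The counts came from 7 of 25 annotated SMUG1 transcripts.

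Replication-dependent histone genes, which encode the nucleosome proteins made in S phase, gave 6 of the 12 largest rises. The libraries were poly(A)-selected, so these counts cover only histone RNA that passed this selection and need not follow total histone mRNA. HIST2H2AA3, on chromosome 1 from 149842188 to 149842736, went from 7.62 ± 3.04 CPM to 129 ± 26.1 CPM (SD, n = 2), a log2 fold change of 4.04 (SE 0.26, adjusted p = 7.37e-13, edgeR). H3C14, next to it, rose by 3.45 on the log2 scale (SE 0.22), and H3C15 rose 9.35-fold. HIST2H2AA4 rose 7.58-fold. These genes have near-identical copies in the same cluster, so the share of each copy is uncertain. H4C15 rose 11.9-fold, through a transcript annotated as subject to nonsense-mediated decay. H2AC20 had 2 counts in wild type and 30 in knockout, a ratio of 12.1 with a 95% exact counting interval of 3.08 to 105. Of the 19 histone genes tested, 16 rose and 0 fell, a family chosen after its values were seen. Their changes lay between 0.23 and 4.04 on the log2 scale.

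**Figure D2:**
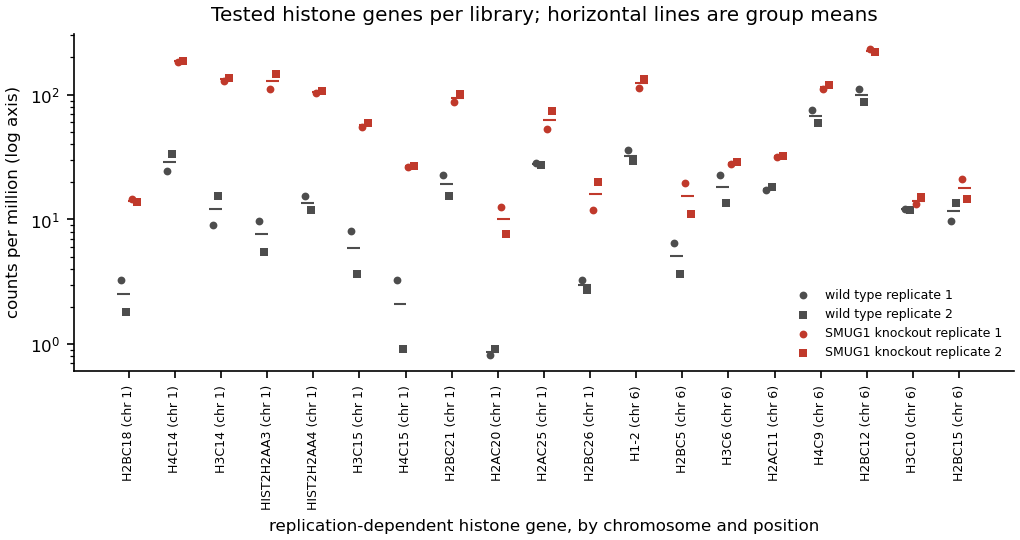
CPM on a log axis for each of the 19 tested replication-dependent histone genes, ordered by chromosome and position, in the 2 wild-type libraries (grey) and the 2 knockout libraries (red), with horizontal lines at group means. All 11 genes on chromosome 1 and 5 of 8 on chromosome 6 were past the threshold.

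The other 6 large rises were unrelated genes. SHC3, an adaptor of receptor tyrosine kinases on chromosome 9 from 89005771 to 89178767, went from 2.54 ± 1.01 CPM to 26.7 ± 1.33 CPM (SD, n = 2; log2 fold change 3.32, SE 0.44, adjusted p = 1.03e-06, edgeR). MANBA, the lysosomal beta-mannosidase gene on chromosome 4 from 102630770 to 102760994, went from 3.86 ± 0.297 CPM to 37.5 ± 0.727 CPM (log2 3.24, SE 0.37). HOXC12, a homeobox gene on chromosome 12, rose 7.22-fold. AXIN1, a scaffold protein of the beta-catenin destruction complex, rose 6.93-fold through a retained-intron transcript. TMEM179 rose 6.56-fold, a call that ended without the first knockout library (adjusted p = 0.109). PDXP, pyridoxal phosphatase, had 3 counts in wild type and 38 in knockout, a ratio of 10.2 with a 95% exact counting interval of 3.25 to 51.8.

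Among the falls, TNFRSF10D, a decoy receptor for TRAIL on chromosome 8 from 23135588 to 23164030, had 16 and 14 counts in the wild-type libraries and 0 in both knockout libraries. It was at least 12.4-fold lower, against a floor of 3 counts over the group. CNNM1, on chromosome 10, had 55 counts in wild type and 1 in knockout, a ratio of 68.0 with a 95% exact counting interval of 11.7 to 2736. EGR3, an immediate early transcription factor gene on chromosome 8, had 27 counts and 1 count, a ratio of 33.4 with an interval of 5.51 to 1368. BMP2, a bone morphogenetic protein gene on chromosome 20 from 6767664 to 6780280, went from 41.9 ± 6.36 CPM to 2.70 ± 0.0868 CPM (SD, n = 2), a 15.1-fold fall (log2 -3.92, SE 0.38, adjusted p = 3.37e-09, edgeR).

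GPR50, an orphan receptor gene related to melatonin receptors on chromosome X, went from 127 ± 5.34 CPM to 16.8 ± 1.37 CPM (SD, n = 2; log2 fold change -2.90, SE 0.20, adjusted p = 1.73e-12, edgeR). CA2, carbonic anhydrase 2 on chromosome 8, went from 209 ± 18.7 CPM to 31.1 ± 2.91 CPM, a 6.71-fold fall. ELP4, a subunit of the Elongator complex, fell 6.84-fold. CKMT1B, a mitochondrial creatine kinase gene with the near-identical copy CKMT1A, fell 7.79-fold. All its counts came from a transcript annotated as subject to nonsense-mediated decay. IFI44L fell 6.33-fold and MAL2 fell 5.46-fold, and both calls ended without the first wild-type library. NPNT, the nephronectin gene, fell 4.77-fold and lost its call in the same way. PREP, prolyl endopeptidase, fell 4.57-fold, and its call ended without the second wild-type library.

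Genes of the heat shock response were lower as a group. Of 10 members tested, 0 rose and 5 fell, or 8 when adjusted over the list alone (camera adjusted p = 4.64e-06). The inducible chaperone gene HSPA1B went from 1251 ± 155 CPM to 486 ± 19.9 CPM (SD, n = 2; log2 -1.36, SE 0.09), and its near-identical copy HSPA1A fell 2.27-fold. The list gave adjusted p = 0.667 with an estimated correlation, a test on 2 residual degrees of freedom.

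Cytosolic ribosomal protein genes were also lower. Of 36 members tested, 0 rose and 13 fell, also when adjusted over the list alone (camera adjusted p = 1.82e-04, median log2 -0.52). RPL8 fell by 1.95 and RPS3A by 1.27 on the log2 scale. The most counted transcript was protein coding for 11 of the 36 genes. The list gave adjusted p = 0.667 with an estimated correlation.

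In fatty acid and triglyceride synthesis, 5 of 10 members fell and 0 rose, with the same 5 falls when adjusted over the list alone (camera adjusted p = 0.0489). ME1, malic enzyme, fell by 1.21 and the elongase ELOVL6 by 1.03 on the log2 scale. The call ended in 11 of 15 alternatives, with adjusted p from 0.0206 to 0.667 over them, and the list gave adjusted p = 0.667 with an estimated correlation. Of 13 mitochondrially encoded mRNAs 5 rose, 0 fell and 8 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0460). The list gave adjusted p = 0.804 with an estimated correlation, which was 0.775 between its genes, and 0.280 with fry's test of movement in 1 direction. MT-ND6 rose 1.66-fold and MT-ND5 rose 1.58-fold, while the median log2 fold change of the list was 0.09. Mitochondrial genes held 19.1% and 19.4% of the counts of the wild-type libraries and 21.8% and 23.9% of those of the knockout libraries, and mitochondrial rRNA 1.34% and 1.35% against 2.29% and 2.45%. This call ended in 6 of 14 alternatives, among them without the second knockout library (adjusted p = 0.442, from 2.42e-05 to 0.804 over the alternatives). Neither fry's test of movement in 1 direction nor the estimated correlation called any of the 26 lists. Fry's mixed test, of change in either direction, called 19, camera called 4 and cameraPR called 3. Of the single genes, 3129 had an unadjusted p under 0.05.

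**Figure D3:**
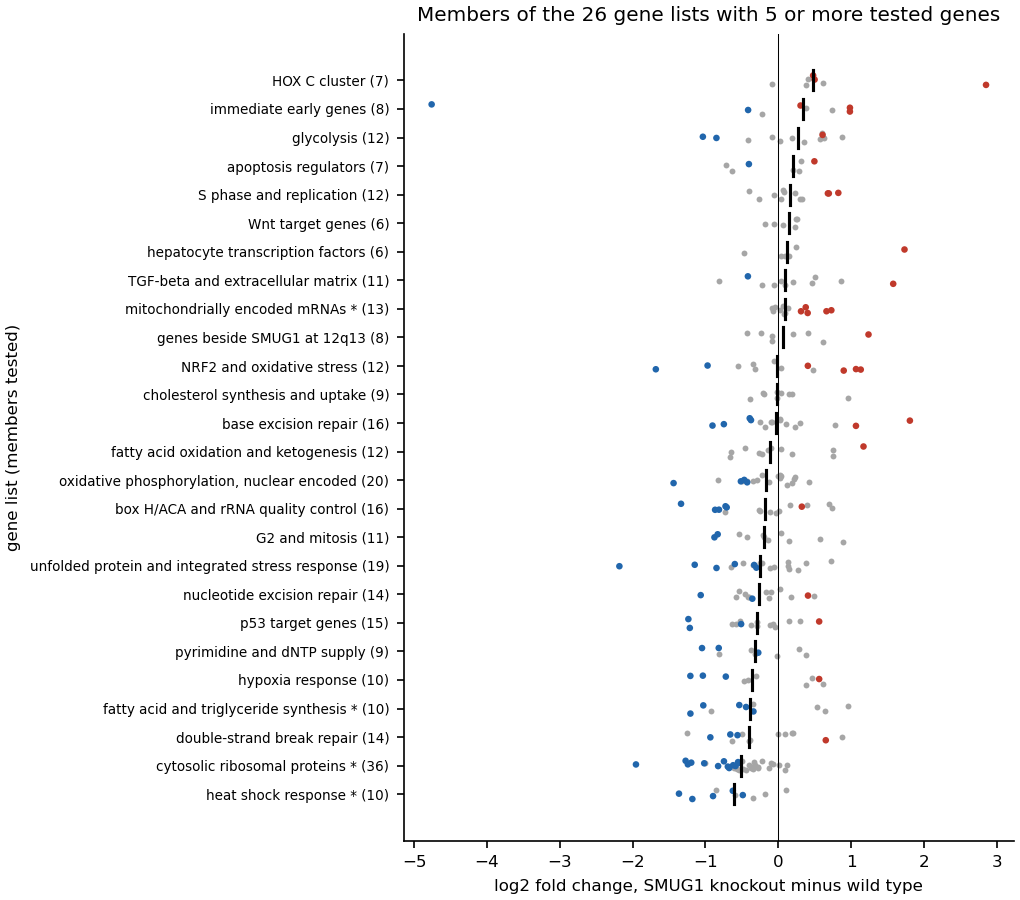
Log2 fold change, knockout minus wild type, of each tested member of the 26 lists with 5 or more tested genes (x axis), with 1 row per list and a black line at its median. Members past the threshold are red (higher) or blue (lower), and the asterisks mark the 4 lists past camera's threshold.

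DNA repair genes went both ways. Among all 8568 genes tested, 25.3% were called, so counts of called members near that share do not set a list apart. Base excision repair, the pathway of SMUG1, had 2 of 16 members higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.791). The glycosylase gene MUTYH rose 3.50-fold and NTHL1 2.09-fold, while the polymerase gene POLL fell by 0.90 and the glycosylase gene NEIL3 by 0.75 on the log2 scale. MUTYH rested on 2 and 3 counts in wild type and 11 and 12 in knockout. The most counted transcripts of NTHL1 (66.1% of its counts) and POLL (60.3%) were not annotated as protein coding. MUTYH, NTHL1, NEIL3 and POLL lie among neighbours that moved the same way, with window medians of 0.63, 0.59, -0.70 and -0.46. With offsets for GC content and length these medians were 0.59, 0.39, -0.60 and -0.58. Nucleotide excision repair had 1 of 14 higher (ERCC4) and 2 lower (GTF2H5 and GTF2H2), unchanged when adjusted over the list alone (camera adjusted p = 0.715). Double-strand break repair had 1 of 14 higher (FANCI) and 3 lower, or 6 lower when adjusted over the list alone (camera adjusted p = 0.284), with PRKDC lower by 1.91-fold and MRE11 by 1.58-fold. FANCI had 90.15% of its counts in a retained-intron transcript. Mismatch repair had 3 members tested, of which RFC3 fell 1.48-fold, also when adjusted over the list alone. Pyrimidine and dNTP supply had 3 of 9 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.284), led by DTYMK and UMPS. Box H/ACA and rRNA quality control, the RNA pathway to which SMUG1 has been linked, had 1 of 16 higher (EXOSC6) and 5 lower, or 6 when adjusted over the list alone (camera adjusted p = 0.442), led by EXOSC1 and NAF1. EXOSC1 had 75% and DTYMK 52.4% of its counts in a retained-intron transcript.

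Cell cycle and death genes gave no list past the threshold. S phase and replication had 3 of 12 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0669), with POLE up 1.77-fold and E2F1 up 1.62-fold. G2 and mitosis had 0 of 11 higher and 2 lower, KIF11 and CDK1, the same adjusted over the list alone (camera adjusted p = 0.284). CDK1 had 73.2% of its counts in a retained-intron transcript. The most counted transcript of POLE (37.8% of its counts) was not annotated as protein coding. Of 15 p53 target genes, PMAIP1 rose 1.48-fold and 3 fell, or 4 when adjusted over the list alone (camera adjusted p = 0.442), with PHLDA3 and FBXW7 falling most. FBXW7 had 89.7% of its counts in a retained-intron transcript. Apoptosis regulators had HRK higher and CFLAR lower among 7, or 2 lower when adjusted over the list alone (camera adjusted p = 0.979). CFLAR, at log2 -0.40, turned to 0.31 with the authors' FPKM and to 0.0119 with regional centring.

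No stress or signalling list other than the heat shock response was past camera's threshold. The unfolded protein and integrated stress response had 0 of 19 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.123). This list was past the threshold in 5 of 15 alternatives, with adjusted p from 0.00548 to 0.667 over them, and HERPUD1 fell by 2.18 and CRELD2 by 1.15 on the log2 scale. NRF2 and oxidative stress had 4 of 12 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.791). In it HMOX1 rose 2.19-fold, and SLC7A11 fell 3.21-fold and TKT 1.96-fold. The hypoxia response had 1 of 10 higher (LOX) and 3 lower, led by BNIP3L and PDK1, also adjusted over the list alone (camera adjusted p = 0.325). Immediate early genes had 3 of 8 higher and 2 lower, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.842), with FOS and JUNB rising most and EGR3 and JUN falling. Of 4 interferon response genes tested, IFI27 rose 2.80-fold, OAS3 rose 1.83-fold and IFI44L fell, also adjusted over the list alone.

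In metabolism, glycolysis had 1 of 12 higher (PKM) and 2 lower (PDK1 and PGAM1), also adjusted over the list alone (camera adjusted p = 0.979). Cholesterol synthesis and uptake had none of 9 past the threshold in edgeR, also adjusted over the list alone (camera adjusted p = 0.979), and SC5D and SQLE, its most abundant members, had log2 fold changes of -0.19 and -0.02. Fatty acid oxidation and ketogenesis had 1 of 12 higher, PPARGC1A, and 0 adjusted over the list alone (camera adjusted p = 0.980), and the median (-0.12) and mean (0.03) of its log2 fold changes differed in sign. Nuclear-encoded oxidative phosphorylation had 4 of 20 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.442), led by NDUFS3 and SDHC. Of 4 urea cycle and amino acid catabolism genes tested, GLUD1 fell 1.85-fold and SLC25A15 fell 1.52-fold, and 0 rose, also adjusted over the list alone. In gluconeogenesis and glycogen, PYGL (log2 -0.18) and UGP2 (log2 0.93) did not pass, over all genes or adjusted over the list alone.

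Among lists of matrix, junction and developmental genes, Wnt target genes had none of 6 past the threshold in edgeR (camera adjusted p = 0.715), with CCND1 at log2 0.06 and ZNRF3 at 0.26. TGF-beta and extracellular matrix had LAMB1 higher and LAMC1 lower among 11 (camera adjusted p = 0.842), and LAMC1, at log2 -0.42, turned to 0.0247 with regional centring. Epithelial junctions and keratins had 2 members tested, of which CLDN1 rose 3.26-fold, and mesenchymal transition had 4, of which PRRX1 rose 1.66-fold. The HOX C cluster had 3 of 7 higher (HOXC12, HOXC13 and HOTAIR) and 0 lower (camera adjusted p = 0.0669), and was past the threshold in 3 of 15 alternatives (adjusted p from 0.00767 to 0.667 over them). Of 8 tested genes beside SMUG1 at 12q13, ATP5MC2 rose 2.34-fold and 7 did not pass (camera adjusted p = 0.668). Adjusted over the list alone, these counts were the same except that junctions and keratins had a further member lower.

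Genes of proteins that hepatocytes secrete were nearly absent from all 4 libraries. Of 25 secreted-protein genes, 0 passed the count filter, 19 had 0 counts in every library, and the whole list held 28 counts. APOB, with 12238 exonic bases that no other transcript shares, had 0 counts, which allows up to 0.552 CPM over the 4 libraries, and AFP and HNF4A also had 0. No member of bile acid synthesis and transport was tested, and 1 of complement and acute phase, C5, had log2 0.19 and did not pass, over all genes or adjusted over the list alone. Of 3 tested drug and xenobiotic metabolism genes, CYP3A5 had log2 0.10 and CYP1B1 0.09, and 0 passed in edgeR, also adjusted over the list alone. Hepatocyte transcription factors had 6 of 20 members tested, of which ATF5 rose 3.31-fold and 0 fell, also adjusted over the list alone (camera adjusted p = 0.513). Of 4 oncofetal and stem-like liver cancer genes tested, SOX9 rose 2.06-fold, and KCNQ1OT1 fell 2.15-fold and LIN28B 1.72-fold, also adjusted over the list alone.

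Marker lists of other cell types were also mostly empty. No endothelial, leukocyte or squamous epithelium marker was tested, nor any NF-kappaB and inflammatory cytokine gene. COL1A1 alone of the fibroblast and stellate list was tested (log2 0.10), and it did not pass, also adjusted over the list alone. Of 12 HEK293 and neural markers 4 were tested, and INA, a neuronal intermediate filament gene, rose from 109.7 ± 21.0 CPM to 259 ± 22.2 CPM (SD, n = 2; log2 1.23), and NES, nestin, rose 1.98-fold, the same 2 as adjusted over the list alone. Both AID and APOBEC deaminases tested, APOBEC3C (log2 0.31) and APOBEC3F (log2 0.03), did not pass over all genes, and 1 was higher when adjusted over the list alone.

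Fold changes also followed position along chromosomes. TNFRSF10D and EGR3 lie on the short arm of chromosome 8 and CNNM1 on the long arm of chromosome 10, where neighbouring genes were also lower. Of the 88 genes named by the rule that were past the threshold and had a window, 21 lay in a window whose median was shifted the same way by at least 0.5. This limit was chosen after the values were seen. Of the 21 genes, 3 were higher and 18 lower. Besides TNFRSF10D, EGR3 and CNNM1, the 21 genes were AXIN1 and NTHL1 on chromosome 16, MUTYH and PHLDA3 on chromosome 1, CKMT1B on chromosome 15, ELP4 on chromosome 11, and CA2 and BNIP3L on chromosome 8. On chromosome 4 they were NEIL3, NAF1, SLC7A11, RPS3A and FBXW7, and on chromosome 10 KIF11, CDK1, PGAM1, GLUD1 and EXOSC1. PRKDC and RPL8 lay in windows of chromosome 8 with medians of -0.07 and -0.09. In the window of 25 tested genes from 19.8 to 29.3 Mb of chromosome 8 the median log2 fold change was -0.67, with 13 genes lower and 0 higher, and in the window from 94.4 to 100.2 Mb of chromosome 10 it was -0.76. These window medians carry no GC or length offsets. With such offsets, the window of AXIN1 went from 0.63 to 0.26 and that of CNNM1 from -0.76 to -0.80. The windows of NTHL1 (0.39), ELP4 (-0.38), CA2 (-0.42), CKMT1B (-0.46), and RPS3A and FBXW7 (-0.46) also dropped below 0.5 in size. Those of the remaining genes among the 21 stayed beyond that limit.

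**Figure D4:**
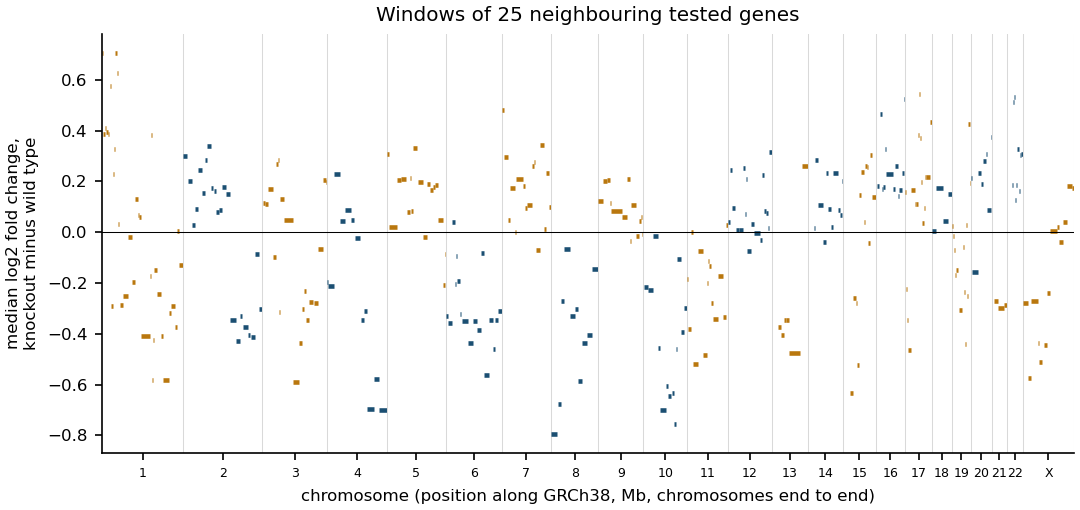
Median log2 fold change, knockout minus wild type, in windows of 25 neighbouring tested genes along the chromosomes of GRCh38 laid end to end, where each bar spans its window. Windows of chromosome 10 reach -0.76 and those of chromosome 8 reach -0.79.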

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

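Transcript IDs outside the gene annotation were left out of the gene comparison. Tested with the deposited transcript table in edgeR, a comparison chosen after seeing the data, 17 of 168 such transcripts were higher in knockout than in the wild-type controls and 14 were lower. These transcripts did not change more often than all 8816 tested, of which 953 were higher and 1225 lower. They came to attention because they carry a difference in data that the gene comparison does not use. The transcript with the lowest adjusted p had 88 and 68 counts in wild type and 169 and 165 in knockout (log2 0.76, SE 0.15). No explanation was tested.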

How the results depend on the processing

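Regional centring, GC and length offsets, transcripts as deposited and coding-led genes were chosen after seeing the data. Against 2170 changed genes (943 higher, 1227 lower), DESeq2 called 806 (256 and 550), all among the 2170. The median dispersion was 0.0567 in DESeq2 and 0.00328 for edgeR's tagwise values. These are unlike measures, since edgeR's test fits a further quasi-likelihood dispersion per gene. Whether they account for the difference in calls was not tested. In DESeq2, 369 of the 2170 had no adjusted p, and without its independent filter it called 732. Limma-trend on FPKM called 765 (281 and 484), a threshold of 0.01 gave 1294 (487 and 807) and glmTreat 284 (124 and 160). The cause of the fall with FPKM was not tested. Regional centring gave 1394, with 763 lower and 1053 shared. Leaving out 1 library gave 1275 to 1807 calls, 510 to 760 higher and 765 to 1105 lower; the fewest came without the first (1336) or second (1275) knockout library, with the lone library assumed to vary like the others. Library size alone gave 1141 higher and 1095 lower and moved the median of all genes by 0.05. These counts and the remaining ones stayed within 1.5 times. SMUG1 passed in none, with log2 -0.01 to 0.23 when 1 library was left out.

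Replicate numbers shared no deviation (r = -0.05 across 8568 genes, which are not independent replicates), and the labels do not pair them. With the replicate block 2095 genes were called and 2 lists. Camera called 4 lists; 0 lists were called with an estimated correlation or by fry's directional test, and 2 without the 20 most abundant genes. Leaving out 1 library gave 3 to 6 lists, with 2 of the 4 among them without the second knockout library. The heat shock and ribosomal protein lists each kept the call in 13 of 15 alternatives, the fatty acid list in 4 of 15 and the mitochondrial list in 8 of 14. Camera called 14 chromosomes, against 0 with an estimated correlation, 10 with no filter, 18 with GC and length offsets and 14 to 15 without 1 library. With an estimated correlation, camera's test has 2 residual degrees of freedom. The estimate was -0.0027 for chromosome 10 and 0.0096 for the ribosomal protein list, both below the preset 0.01. A larger correlation therefore does not account for the loss of these calls. For the heat shock, fatty acid and mitochondrial lists it was above the preset (0.0863, 0.0607 and 0.775). The causes of the other differences were not tested.

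For the 24 genes named by size, 405 of 411 values kept direction and call and 6 lost the call. For 118 list members, 1727 of 2066 kept both, 330 lost the call, 4 gained it and 5 reversed: CFLAR (0.31 with FPKM, 0.0119 with regional centring) and, with regional centring, LAMC1 (0.0247), APEX2 (0.0478) and SCD (0.17), where the cause is the offset of the region. The causes of the lost calls were not tested. The median tested gene had 36.3 counts per library, and 26.2% of simulated 1.5-fold changes were recovered.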

Other observations

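Some gene families outside the fixed lists were counted after their values were seen, with no test of the families. Over all 8568 genes tested, 943 rose and 1227 fell. Of 39 EIF translation initiation factor genes tested with edgeR, 0 rose and 13 fell, and of 166 ribosomal protein pseudogenes 0 rose and 43 fell. Reads of these pseudogenes and of ribosomal protein genes cannot be told apart with certainty. The pseudogene falls are therefore not separate evidence from the 24 falls and 0 rises among 68 ribosomal protein genes. Of 39 mitochondrial ribosomal protein genes 4 rose and 6 fell, and of 27 HOX genes 9 rose and 3 fell. In 3 of 825 genes with several tested transcripts, 1 transcript rose and another fell: BRWD1, RPS15A and SCAF11, also named after their values were seen. In RPS15A, a protein-coding transcript with 5 counts in wild type and 31 in knockout changed by 2.24 on the log2 scale and another by -0.95.

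All tests of explanations below were chosen after the patterns were seen, except that the chromosome comparison was planned.

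Of hepatocyte lists, the members with a mean of 10 counts were 0 of 25 for secreted proteins (median of matched random lists 6), 0 of 16 for bile acids (5), 1 of 25 for complement (9), 3 of 25 for drug metabolism (7), 3 of 21 for the urea cycle (6) and 6 of 20 for transcription factors (7), with ONECUT2 at 409 CPM. Counting only reads that fit 1 transcript is argued against as the cause of the near absence of secreted-protein genes: 19 of 25 secreted-protein genes had no count, and 100% of 10000 random protein-coding lists matched on exonic bases of their own had fewer. A mixture with leukocytes, endothelium, fibroblasts or squamous cells is also argued against, since 100% of matched lists had more members with a mean of 10 counts than the 1 of 52 markers seen. Cells of a HEK293-like or neural line cannot be told apart from other origins: 5 of 12 markers reached that mean, more than in 52.8% of matched lists, with ZIC2 at 297 CPM and SOX2 at 38.8 CPM, and the oncofetal gene IGF2BP1 at 1187 CPM, but PAX8 and NEFL at 0 counts. The near absence of secreted-protein genes argues against cells with the hepatocyte expression that the label HepG2 implies. The transcription factor list lay near its random median and does not decide. Which line the cells were stays open, and no biological explanation was tested.

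Of 23 chromosomes, 14 differed from the rest by camera and by cameraPR, 15 moved by fry, and 0 differed with an estimated correlation (adjusted p = 0.0879 for chromosome 10). On chromosome 10, 137 of 329 genes were lower and 11 higher (median log2 -0.46); on chromosome 16, 77 of 407 were higher and 9 lower. GC content and length do not account for all of it. After their correction the SD of window medians was 0.286, against at most 0.225 in 1000 shuffles of gene order within chromosomes. Some upward shifts shrank: on chromosome 16 the median of the window from 0 to 1.3 Mb went from 0.63 to 0.26. Camera's adjusted p for that chromosome went from 6.76e-06 to 0.00157. The window from 94.4 to 100.2 Mb of chromosome 10 went from -0.76 to -0.80. Co-regulation of immediate neighbours alone is argued against by r = 0.396 across genes between a gene and those 5 to 20 Mb away, against at most 0.0442 when shuffled. The value after correction, 0.373 against at most 0.0477, is what segments of different copy number in the 2 groups could give. No DNA measurement tests this hypothesis here, and an effect of SMUG1 loss cannot be separated from it for genes in such segments. For all other genes, clone, culture and library preparation may also differ with the group, so no change can be credited to SMUG1 loss alone.

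The histone rise was largest in the chromosome 1 cluster, where 9 of 9 tested genes rose by a median of 3.22 on the log2 scale. Weaker poly(A) selection of the knockout libraries could not be decided. The 23 tested small and ribosomal RNA genes had a median log2 fold change of -0.35 (SE of the median 0.23). This lay below the limit of 1.14, which is 0.5 times the histone median. Many such RNAs are short, however, and may be lost from libraries whatever the selection. Mitochondrial rRNA went the other way, from 1.34% and 1.35% of counts in wild type to 2.29% and 2.45% in knockout. The whole mitochondrial share rose as well, from 19.1% and 19.4% to 21.8% and 23.9%. LincRNA genes assigned to ribosomal DNA (FP236383 and FP671120) fell, from 1.14% and 0.607% in wild type to 0.451% and 0.449% in knockout. These markers went both ways and do not decide. A copy gain of the region around the cluster is argued against by the 39 other genes within 2 Mb, with a median of -0.41 (SE 0.14). A gain confined to the cluster could not be tested this way, since those neighbours would lie outside it. Exchange of reads between near-identical copies is argued against because the summed CPM of the cluster rose by 3.02 on the log2 scale. The S phase and replication list had a median log2 fold change of 0.16, with 3 of 12 members higher and 0 lower. The median was 0.82 for the 8 histone genes on chromosome 6 and 2.27 for all 19. These values do not decide on cell cycle timing. Altered transcription, 3' end processing or cell cycle timing stay open as untested hypotheses, as does an effect of SMUG1 loss.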
